A study of Mus musculus with 5 samples.

How the data were processed

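Single-cell RNA libraries were made from mouse cochlea at postnatal days 30 to 33, per the labels, from 2 control and 3 CKO samples. The control samples carry replicate numbers 4 and 5, and the CKO samples 4, 5 and 6. All 5 carry a bhlhb5-Cre transgene and a tdTomato reporter, and the CKO samples also carry floxed Runx1, per the labels. Tissue from both sexes was dissociated with collagenase and papain and sorted for tdTomato-positive spiral ganglion neurons, per the labels. Libraries were made with the 10x Genomics 3' assay and sequenced on a NextSeq instrument, per the labels' protocols.

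The submitters' processing notes name Cell Ranger, Seurat and the genome build mm10, without versions. The authors deposited 1 matrix of 14715 genes by 1954 cells in natural log units, ln(1 + 100000 × UMI count / cell total). This unit was settled from the values. The exponential of each value minus 1 summed to 100000 in every cell, and 100% of values above 0 gave a whole UMI count within a tolerance of 0.01. UMI counts recovered in this way from the deposited natural log values were used wherever UMIs, depths or thinned cells are reported. How the authors chose cells and genes is not stated in the sources used here. The lowest cell held 10379 UMIs and 4003 genes, every gene was seen in at least 5 cells, and the matrix held 0 genes of the mitochondrial genome. The plan made before the data were examined assumed values that could be assigned to libraries.

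The column names are bare barcodes, and a separate deposited record gives the genotype of each cell and not its library. Each genotype was therefore treated as 1 pool, control with 1070 cells and CKO with 884. Cells are not replicates, so no p-value or test between genotypes was computed, and no standard error over cells or libraries. Standard errors given for positions between control and CKO are bootstraps over genes. They take genes as separate draws although genes of a class vary together, so they may be too small. Intervals are exact 95% intervals, Poisson for UMI counts and Clopper-Pearson for shares, and cover counting error only. For a share of 0 the share that 3 counts would give is printed, with the exact upper bound beside it. Barcodes restart their alphabetical order along the columns and so form 5 column stretches, 1, 3 and 4 with CKO cells and 2 and 5 with control cells. Their number equals the number of libraries, but no source used here says which library a stretch is. Stretches were noticed after seeing the data. They were used to give values, to leave out 1 stretch at a time, to place each CKO stretch between the others and control, to part the stretches 2 against 3 and to compare neurons within a stretch, never as replicates. One barcode occurs in both genotypes, so cells were joined by position.

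Gene levels are UMIs per 10000 UMIs of a cell, averaged over cells, and log2 values are log2((CKO + 0.1)/(control + 0.1)). Genes were counted as at least 2-fold apart where the mean reached 0.5 in either genotype. The rule for named genes was set before the data were examined. It takes Runx1, then the 10 genes each way with the largest log2 value at that mean, without predicted, sex-linked or mitochondrial genes. All members of the marker lists for types Ia, Ib, Ic and II follow, then up to 4 members of each other list at a mean of 0.2 or more, and 5 genes each way within each class. Some genes that this rule names are left out of the text because they are withheld for evaluation. The 31 gene lists were fixed at the same time. The median log2 value of each list was set against 10000 random lists of the same size matched on mean level in 20 bins, and a list counts as outside where its median left the central 95% of these.

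Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on 2000 variable genes and 20 principal components at resolution 1, under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Clusters were named from markers fixed beforehand. These were Calb2, Rxrg, Pcdh20 and B3gat1 for type Ia, and Calb1, Lrrc52 and Ttn for type Ib. Lypd1, Pou4f1, Grm8 and Runx1 stood for type Ic, and Prph, Th, Etv4, Plk5, Ngfr and Smad3 for type II. Runx1 was left out of every score. The type Ib name rests mainly on Calb1 and Ttn, since Lrrc52 reached a mean of only 0.0375 in control neurons. Among control clusters, 1 of 28 cells named type Ib and 1 of 47 cells named type II had none of their own markers among their top 10 genes. The second was led by Apoe and Fabp7, which glia express, and shared Dupd1, Hspb1 and Myl1 with the other type II cluster. All 1954 cells fell into 19 clusters with neuronal markers, so all entered as neurons.

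For each type I class of the control cells, the 50 genes with the highest ratio to the other type I classes were taken, without Runx1, at a class mean of at least 0.5. Each type I neuron of either genotype was then given the class whose control profile over these 148 genes had the highest correlation with its own. This is a nearest-profile call, not a cell type. Of the 948 control type I neurons, 97.6% were given the class of their own cluster. Shares of cells with a UMI were computed after thinning every cell to 10000 UMIs, and all cells were deep enough to stay. No doublet caller was run, and doublets were weighed by UMI counts. Neurons with at least 5 UMIs per 10000 from the Schwann and satellite glia list were called glia-high, a value chosen after seeing the data.

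Gene coordinates come from the GENCODE vM21 annotation of mm10 (GRCm38), in which 14124 of the 14715 symbols were found. The matrix gives symbols only. Rps2, Rpl21 and Rpl29 have near-identical copies in the genome and Cwc22 has further copies, so their levels are uncertain where counting split such reads.

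The procedure was tested on simulated counts drawn from the control means and each cell's depth, with a gamma spread between cells and planted changes, and 3678 genes reached the floor. Of 50 genes raised by a factor of 4, 100% passed the 2-fold rule, as did 100% of 50 genes lowered to 0.25. Of genes raised by 2, 0% passed, and of genes lowered to 0.5, 72% passed. Planting lowered the median log2 value of the other genes to -0.10, and 0 of 3478 unplanted genes passed. Random lists left the 95% range in 2% of draws. In these simulations of folds and lists each pool had 1 mean profile, without classes and without differences between stretches. They therefore do not show how often such differences pass the rule or move a list in the real data. All simulated CKO neurons were given their own class. The simulated classes lay apart by a factor of 4, more than most set genes of the real classes, so this does not measure how accurate the calls are here.

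Alternatives planned before the data were examined were 2 other pseudocounts, 2 other filters, median ratio scaling, summed UMIs, neurons without type II-like cells, other set sizes and resolutions, sets chosen in random parts of the control cells, a lead of at least 0.05 between classes, class calls without 11 genes, 2 UMIs as the threshold and no thinning. Leaving out each column stretch and using glia-poor cells only were added after seeing the data, as were gene lists without type II-like cells.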

Results

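RNA was counted in 1954 single neurons of the mouse spiral ganglion, the cells that carry sound signals from the cochlea to the brain. Each captured molecule carries a unique molecular identifier (UMI), and levels are given as mean UMIs per 10000 UMIs of a cell. The animals were 30 to 33 days old and of both sexes, and neurons were enriched by sorting for a tdTomato reporter that Cre recombinase switches on. The 2 control samples carried bhlhb5-Cre and the reporter, and the 3 CKO samples carried floxed Runx1 as well. Runx1 is a transcription factor, and the comparison asks how its loss bears on the diversity of auditory neurons. Control gave 1070 neurons with 40734464 UMIs and a median of 38085 per cell, and CKO gave 884 neurons with 37482099 UMIs and a median of 44120.5. Cells ranged from 10379 to 100856 UMIs.

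Cells could be assigned to a genotype but not to a sample, so each genotype is 1 pool without replicates. Differences below compare these pools, and their intervals cover counting error only. The cells lie in 5 column stretches of 355 (CKO), 482 (control), 372 (CKO), 157 (CKO) and 588 (control) cells, numbered 1 to 5 in this order, whose libraries the sources used here do not name. Type II-like neurons, which serve outer hair cells, made up 17.2% of CKO cells (152 of 884, exact 95% interval 14.8 to 19.8) and 11.4% of control cells (122 of 1070, 9.56 to 13.5). By stretch the share was 16.6%, 15.6%, 18.8%, 14.7% and 7.99%, and the sort can set it. RNA of Schwann and satellite glia was present in 55.4% of CKO neurons and 61.2% of control neurons at 5 or more UMIs per 10000. Across the stretches this share was 49.6%, 49.0%, 64.5%, 47.1% and 71.3%.

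Runx1 RNA was not lower in the CKO neurons. Its mean was 1.68 in CKO and 1.23 in control (log2 0.42), with 6607 and 4942 UMIs and a ratio of UMI rates of 1.45 (exact 95% interval 1.40 to 1.51). The stretch means were 2.01, 1.34, 1.46, 1.44 and 1.14. Runx1 lies on chromosome 16 from 92601466 to 92826149 on the minus strand (mm10). The assay reads the 3' end, and the labels do not say which part of the gene was deleted, so these counts do not check the deletion.

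More type I neurons, which serve inner hair cells, were nearest the type Ia profile in CKO than in control. Of 732 CKO type I neurons, 62.6% (exact 95% interval 58.9 to 66.1) were nearest type Ia, the class with high Calb2. Another 21.0% (18.1 to 24.2) were nearest type Ib, which expresses Calb1, and 16.4% (13.8 to 19.3) were nearest type Ic, which expresses Lypd1. Of 948 control type I neurons, 26.4% (23.6 to 29.3), 40.3% (37.2 to 43.5) and 33.3% (30.3 to 36.4) were nearest types Ia, Ib and Ic.

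The shares nearest type Ia differed within each genotype. They were 73.0%, 73.8% and 14.2% in CKO stretches 1, 3 and 4, and 12.04% and 37.2% in control stretches 2 and 5. CKO stretch 4 thus lay near control stretch 2, and its neurons were 44.0% nearest type Ib and 41.8% nearest type Ic. Without stretch 4 the CKO share nearest type Ic was 10.7%, and without stretch 5 the control share nearest type Ia was 12.04%. The best class led the next by under 0.05 in correlation in 19.5% of CKO (143 cells) and 4.54% of control type I neurons (43 cells). By stretch this share was 28.4%, 4.67%, 18.5%, 2.24% and 4.44%, so CKO stretch 4 lay below both control stretches. CKO neurons nearest type Ia were less like that profile than control ones, with a median best correlation of 0.805 against 0.854 and a median lead of 0.167 against 0.242. The profile was built from these same control cells, which favours their fit, so the size of this difference is uncertain.

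**Figure D1:**
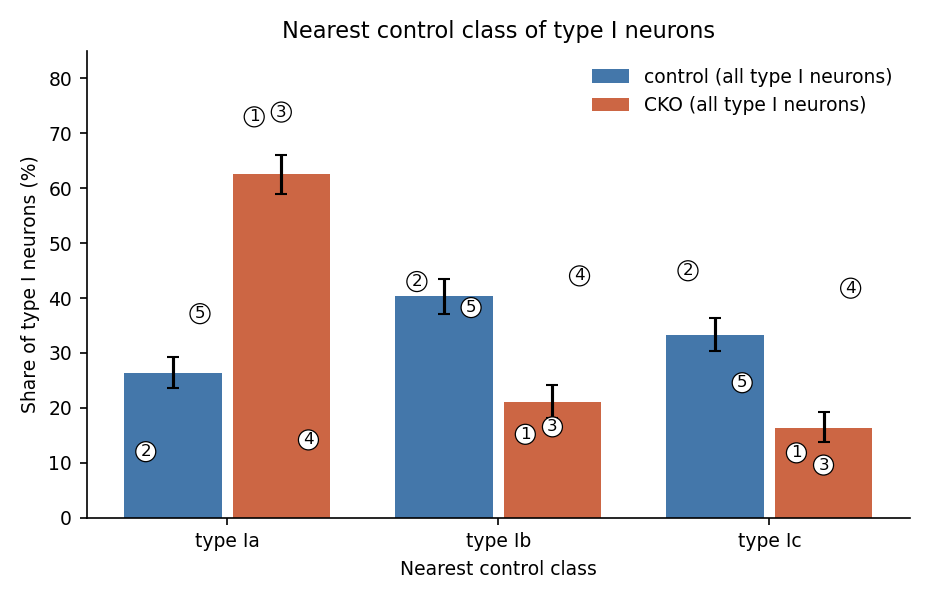
Share of type I neurons (%) nearest each control class, with bars for the genotype pools, exact 95% intervals for counting error and numbered circles for the column stretches. The type Ia share was 62.6% in the CKO pool and 26.4% in the control pool, with CKO stretch 4 at 14.2%.

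Gene sets taken from control classes differed between the pools in the same direction. The class calls used these same genes, so this is not separate support for the shares. Among type I neurons, the median log2 value of the 50 type Ia genes was 0.24, above control, with 42 of 50 higher. The medians were -0.29 for the type Ib set, with 42 of 50 lower, and -0.35 for the type Ic set, with 45 of 50 lower. Among 10000 matched random lists these medians stood at percentiles 100, 0 and 0. Set genes vary together with class, which lists matched on mean level do not, so the percentiles are no support beyond the class shares. Leaving out 1 stretch kept all 3 signs but moved the medians of type Ia between 0.10 (without stretch 2) and 0.61 (without stretch 5) and of type Ic between -0.16 and -0.55 with the same stretches. Single stretches differed in sign within a genotype. Against the control pool, CKO stretches 1 and 3 had medians of 0.34 and 0.39 for type Ia, -0.40 and -0.31 for type Ib and -0.52 and -0.56 for type Ic, whereas CKO stretch 4 had -0.32, 0.05 and 0.21. Control stretch 5 had 0.19, -0.04 and -0.20 and control stretch 2 -0.30, 0.05 and 0.23.

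In all neurons, 3784 genes reached a mean of 0.5 in either genotype, of which 7 were at least 2-fold higher and 3 at least 2-fold lower in CKO. The median log2 value of these genes was -0.02. The counts were 3 higher and 1 lower without stretch 1, 12 and 11 without stretch 5, and 5 and 7 lower without stretches 3 and 4. Calb1, which encodes the calcium buffer calbindin, had a mean of 0.573 in control and 1.68 in CKO (log2 1.40), with 2395 and 6833 UMIs and a ratio of UMI rates of 3.10 (2.96 to 3.25). Sh3bgr had 0.443 in control and 1.17 in CKO (log2 1.23), and B3gat1, a glucuronyltransferase of the HNK-1 glycan, 0.738 and 1.44 (log2 0.88). The ribosomal protein gene Rps2 had 0.918 and 2.30 (log2 1.24) and Cwc22, a splicing factor, 0.372 and 0.850 (log2 1.01). Eid2 had log2 0.89 and Ppp1r14b, a phosphatase inhibitor, 0.84. Ceacam10 (0.246 and 0.795, log2 1.37) and Ptgds, which makes prostaglandin D2 (0.601 and 1.32, log2 1.02), were high in neurons with glial RNA. In glia-poor cells only, chosen after seeing the data, their log2 values were 0.18 and 0.11. Ptgds had a mean of 0.00636 in glia-poor cells, far under the 0.1 added to each mean, so its value there cannot show whether the genotypes differ. Dupd1 (log2 0.95), a dual-specificity phosphatase, is a type II-like gene here, and its value was 0.19 without type II-like cells. Without stretch 1 the value of Cwc22 was 0.28, and without stretch 5 Ptgds, Cwc22 and B3gat1 had 1.86, 1.68 and 1.53.

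Lower in CKO were Btbd9, with 9.91 in control and 3.59 in CKO (log2 -1.44, UMI rate ratio 0.349, 0.342 to 0.356), and Lypd1, a modulator of nicotinic receptors, with 10.6 and 4.32 (log2 -1.27, UMI rate ratio 0.415, 0.407 to 0.422). Rnf123, a ubiquitin ligase, had 1.42 and 0.633 (log2 -1.05). Log2 values between -1 and 0 were seen for Kcnip2, a subunit of A-type potassium channels (0.504 and 0.229, log2 -0.88), the giant sarcomere protein Ttn (0.554 and 0.264, log2 -0.85) and Rbfox3, the neuronal splicing factor NeuN (0.989 and 0.524, log2 -0.80). Cpne9 (log2 -0.72), the apoptosis inhibitor Faim2 (-0.71), the synaptic scaffold Homer2 (-0.70) and the lectin Lgals1 (-0.66) completed the 10. All of the 10 but Homer2 belong to the type Ib or type Ic sets, and fewer CKO neurons were nearest those classes. Btbd9 and Lypd1 stood at -2.25 and -2.36 without stretch 4. Ttn was -0.08 without stretch 2 and -1.43 without stretch 5. The 20 genes kept their direction with each stretch left out in turn, and 1 higher and 3 lower predicted or sex-linked genes were passed over.

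**Figure D2:**
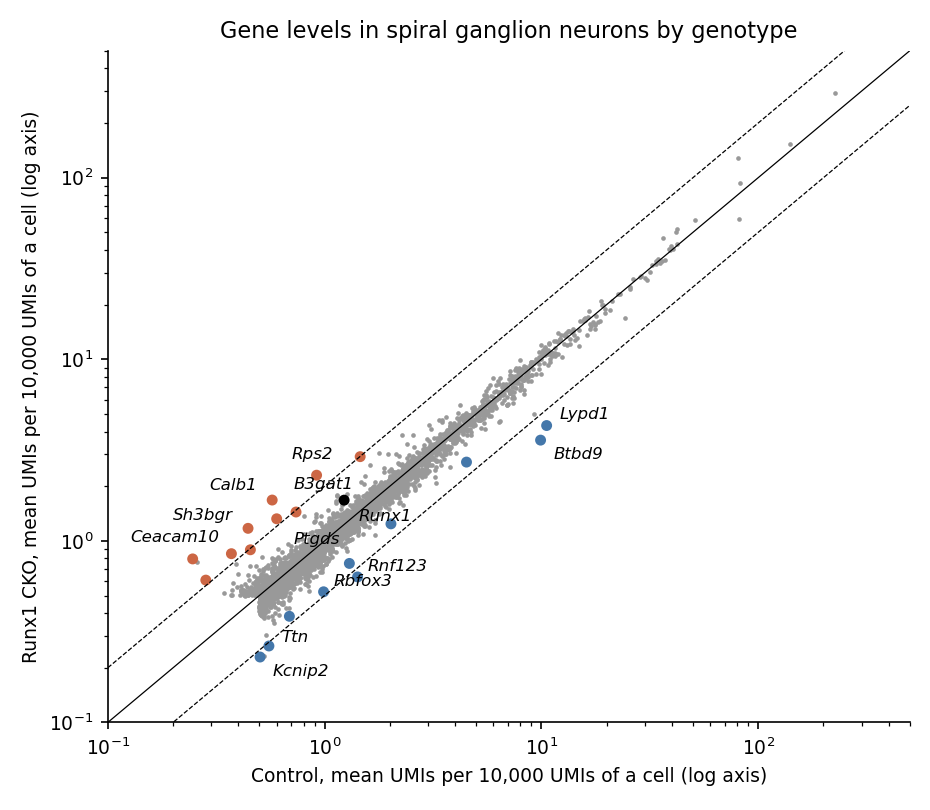
Mean level of each gene in control (x axis) and CKO (y axis) neurons, in UMIs per 10000 UMIs on log axes, for the 3784 genes at the floor, with a line of equal levels, dashed lines at 2-fold, the 10 genes each way in colour and Runx1 in black. Calb1 lies above the line of equal levels at 0.573 and 1.68, and Lypd1 below it at 10.6 and 4.32.

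All 4 type Ia markers were higher in CKO. Calb2, which encodes calretinin, had 80.7 in control and 128 in CKO (log2 0.66, 0.26 without stretch 2 and 1.38 without stretch 5), the retinoid receptor Rxrg log2 0.47, the adhesion protein Pcdh20 0.41 and B3gat1 0.88. Rxrg had stretch means of 0.260, 0.177, 0.490, 0.188 and 0.258 and log2 0.07 without stretch 3. B3gat1 had a mean of 0.311 in CKO stretch 4, against 0.435 and 0.986 in control stretches 2 and 5. Of the type Ic markers other than Runx1, Lypd1 was lower, as were the transcription factor Pou4f1 (0.406 and 0.270, log2 -0.45) and the glutamate receptor Grm8 (log2 -0.33). Without stretch 2 Pou4f1 had -0.10 and Grm8 -0.17, without stretch 3 Grm8 had -0.05, without stretch 4 -0.63, and without stretch 5 Pou4f1 had -0.79. CKO stretch 4 had means of 0.456 for Pou4f1 and 0.447 for Grm8, against 0.541 and 0.320 in control stretch 2 and 0.296 and 0.230 in control stretch 5. The type Ib markers went apart, Calb1 higher and Ttn lower, with Lrrc52 near the detection limit at 0.0375 and 0.0189. Among type II markers, Prph, the intermediate filament peripherin, had 0.317 and 0.146 (log2 -0.76), which turned to 0.80 without stretch 2 and stood at -1.61 without stretch 5. Th, the enzyme of dopamine synthesis (log2 0.23), the kinase Plk5 (0.16) and the neurotrophin receptor Ngfr (0.24) took the other sign with -0.25 for Th and -0.0155 for Ngfr without stretch 3 and -0.28 for Plk5 without stretch 5. The transcription factors Etv4, with 4 UMIs in control and 1 in CKO, and Smad3 (0.0101 and 0.0256) lay under the floor.

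After thinning to 10000 UMIs, Calb1 was seen in 47.5% of CKO neurons (exact 95% interval 44.2 to 50.9) and 26.2% of control neurons (23.6 to 28.9), and Lypd1 in 17.9% (15.4 to 20.6) and 33.6% (30.7 to 36.5). Both were seen together in 9.05% (7.24 to 11.1) and 3.93% (2.84 to 5.27), or 5.77% (4.33 to 7.52) and 0.467% (0.152 to 1.09) with at least 2 UMIs required of each. Without stretch 1 the CKO share with both was 5.29%, and without stretch 2 the control share was 2.38%. Calb2 was seen in 86.5% of CKO and 82.5% of control neurons, Rxrg in 24.4% and 17.4%, Pcdh20 in 33.9% and 21.8%, Pou4f1 in 18.4% and 25.05%, Grm8 in 14.5% and 18.7%, and Prph in 4.86% and 5.61%. Calb2 was seen with Calb1 in 46.5% and 25.9%, and with Lypd1 in 13.5% and 24.3%. Unthinned, the shares with Calb1 were 60.5% and 39.7%, with Lypd1 22.1% and 40.4%, and with both 15.2% and 11.1%.

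As background, type II-like neurons, with median depths of 27019 (CKO) and 25421 UMIs (control) against 47615 and 39413.5 in type I, held a Calb1 UMI in 0.658% of CKO cells and in 0 of 122 control cells, where 3 counts would give 2.46% (exact upper bound 2.98%). Their Lypd1 shares were 1.32% and 3.28%, and their Calb2 shares 47.4% and 26.2%. Rxrg (42.1% and 44.3%), Pcdh20 (87.5% and 90.2%) and Grm8 (14.5% and 13.1%) were also present in type II-like neurons. In type I neurons alone, CKO and control held Rxrg in 20.8% and 13.9%, Pcdh20 in 22.8% and 13.0% and Grm8 in 14.5% and 19.4%.

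Of 31 fixed gene lists, 25 had members at a mean of 0.2 or more, and the medians of 10 lay outside the range of random lists, 5 above and 5 below. Potassium channel genes, which shape firing, had a median log2 value of -0.27 over 17 members (percentile 0). Of these, 1 was at least 1.5-fold lower and 1 at least 1.5-fold higher in CKO. Beside Kcnip2, a type Ic set gene, lower members included Kcnab2 (3.79 in control and 2.56 in CKO, log2 -0.55) and Kcnip1 (log2 -0.43), whereas the silent subunit Kcns3 was higher (0.231 and 0.443, log2 0.72). Different class shares can enter this median, and the list was not run within classes. The type Ia list (median 0.56, percentile 100) and the potassium channel list stayed outside with each stretch left out, the former at 0.34 without stretch 2 and 1.03 without stretch 5, the latter between -0.15 (without stretch 1) and -0.31 (without stretch 5). With no filter on low levels the potassium channel median was -0.02 (percentile 24.2), within the random range.

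The other 8 calls each ended with some stretch left out. The type Ic list (median -0.39, percentile 0) had -0.13 without stretch 2 and -0.18 without stretch 3. The type Ib list (0.28, 99) rested on Calb1 and Ttn and had 0.13 without stretch 4 and 0.00 without stretch 5, and -0.21 with no filter. The type II list (0.19, 99.5, with a mean of -0.03 of the other sign) had -0.13 without stretch 3. Glial genes (-0.23, 0.45) had 0.16 without stretch 5, with the myelin gene Mbp lower (4.04 and 3.03) and the lipid-binding Fabp7 higher (0.288 and 0.358) in CKO. Glutamate receptor genes (-0.16, 1.26) had -0.07 without stretch 3, with Grik4 at log2 -0.48 and Grin1 at -0.31. Receptor genes for GABA, glycine and acetylcholine (-0.19, 1.65) had -0.12 without stretch 2, with Chrnb2 at -0.25 and Gabbr2 at 0.28. Neurotrophin and survival genes (0.10, 97.9) had -0.02 without stretch 3, with the GDNF receptor Gfra1 at 0.36 and Ntrk3 at -0.22. Ribosomal protein genes (0.06, 99.7) had 0.01 without stretch 3.

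Type II-like cells, a larger part of the CKO pool, held 5.94% (CKO) and 5.84% (control) of their UMIs in ribosomal protein genes, against 2.83% and 2.85% in type I neurons. In type I neurons alone, a comparison of lists chosen after seeing the data, 7 lists lay outside the random range, 5 of them among the 10 above. The ribosomal median was then -0.04 (percentile 11.4), the neurotrophin median -0.03 (52.9) and the type II list -0.03 (54.0, 1 member), each of the other sign and within the random range. Glutamate receptor genes (-0.12, 7.66) and receptors for GABA, glycine and acetylcholine (-0.14, 7.47) also lay within it. The lists for types Ia (0.61), Ib (0.33) and Ic (-0.36), glia (-0.23) and potassium channels (-0.18) stayed outside, and cadherins (0.14, 98.8) and oxidative phosphorylation (0.06, 99.7) lay above it.

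The medians of the other 15 lists lay between -0.11 and 0.18, within the range of random lists. These were genes of all spiral ganglion neurons (-0.08), fibroblasts (-0.02), the Runx family (0.18), calcium binding (0.02), sodium and HCN channels (-0.11), calcium channels (0.01), synaptic release (-0.04), cadherins (0.10), other adhesion proteins (-0.03), axon guidance (-0.09), sensory neuron transcription factors (-0.06), the cytoskeleton (0.03), oxidative phosphorylation (0.02), immediate early and stress genes (0.06) and axon injury (0.04). Single members differed more, among them the calcium sensor Hpcal1 (1.14 in control and 1.79 in CKO, log2 0.60), Syn3 of synaptic vesicles (log2 -0.55), the axonal ligand Ntng1 (1.71 and 1.08, log2 -0.63) and the respiratory subunit Cox7b (24.4 and 17.0, log2 -0.52). The 6 lists for endothelial cells, macrophages, hair cells, supporting cells, erythrocytes and the mitochondrial genome had 0 members at that level.

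Within the neurons nearest type Ia, 10 genes were at least 2-fold higher and 5 at least 2-fold lower in CKO. Calb1 had 0.222 in control and 2.01 in CKO (log2 2.72), Ntng1 0.0563 and 0.682 (log2 2.32), and Slc17a6, a vesicular glutamate transporter, 0.233 and 0.824 (log2 1.47). Ntng1 belongs to the type Ib and type Ic sets, Slc17a6 to the type Ic set and Calb1 to the type Ib set. After thinning, 52.8% of 458 CKO neurons nearest type Ia and 13.6% of 250 control neurons held a Calb1 UMI. For Ntng1 the shares were 35.6% and 5.60%, against 13.8% and 21.3% in type II-like neurons. Rps2 (log2 1.70) and Ceacam10 (log2 1.58) were higher as well. At least 2-fold lower were the lipid droplet protein Plin2 (log2 -1.10), the glycogen phosphorylase Pygm (-1.07) and Lgals1 (-1.07), with the predicted gene Gm1821 (-1.30) and the Y-linked Ddx3y (-1.02), which the rule for named genes leaves out and which were named after their values were seen. The secretory chaperone Scg5 (-0.70) and the transcription factor Zbtb20 (-0.67) were lower by less. Without stretch 5 Calb1 had 1.85, Ceacam10 0.83 and Scg5 0.86, and without stretch 1 Pygm had -2.04 and 3 genes were lower.

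Runx1 RNA also differed in these neurons. After thinning, 63.3% (58.7 to 67.7, 290 of 458) of CKO neurons nearest type Ia held a Runx1 UMI, against 13.2% (9.26 to 18.04, 33 of 250) in control, with means of 1.81 and 0.157. By stretch the share was 74.5% (161 of 216), 16.3% (8 of 49, 7.32 to 29.7), 57.4% (128 of 223), 5.26% (1 of 19, 0.133 to 26.03) and 12.4% (25 of 201). The shares nearest type Ib were 84.4% in CKO and 77.7% in control, and nearest type Ic 85.8% and 80.7%. Type II-like neurons held a Runx1 UMI in 0 of 152 CKO cells, where 3 counts would give 1.97% (exact upper bound 2.40%), and in 1 of 122 control cells, at median depths of 27019 and 25421 against 49024 and 47906 UMIs nearest type Ia. Runx1 took no part in the class calls, and this comparison was chosen after seeing the data.

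**Figure D3:**
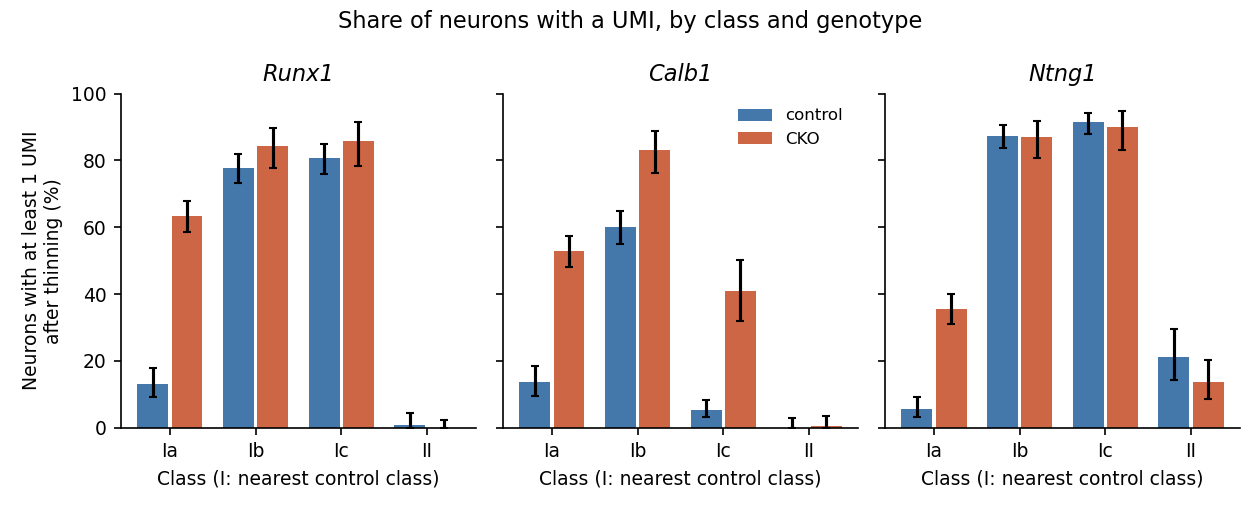
Share of neurons (%) with at least 1 UMI of Runx1, Calb1 or Ntng1 after thinning to 10000 UMIs, for control and CKO neurons by nearest type I class and in type II-like neurons, with exact 95% intervals for counting error. In neurons nearest type Ia the Runx1 share was 63.3% in CKO and 13.2% in control, and the Calb1 share 52.8% and 13.6%.

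In neurons nearest type Ic, 14 genes were at least 2-fold higher and 1 was lower in CKO. Calb1 had 0.0864 in control and 1.19 in CKO (log2 2.79), B3gat1 0.0782 and 0.923 (log2 2.52) and Sh3bgr 0.335 and 1.49 (log2 1.87). The calmodulin-binding Pcp4 (log2 2.70) had 654 UMIs in CKO, in only 9.17% of cells, and Ceacam10 had log2 1.68. The 1 gene at least 2-fold lower was the Y-linked Ddx3y (-1.45), named after its value was seen. Ddx3y was among the genes that set stretches 1 and 4 apart from the rest by at least 1.5-fold in type I neurons. The mix of sexes may thus differ between stretches and pools, and it cannot be told apart from genotype for this gene. Lower by less were Rpl21 (-0.93), Rpl29 (-0.87), Cd164l2 (-0.87), the folate enzyme Mthfd2 (-0.79) and Btbd9 (-0.79). Without stretch 4, 22 genes were higher and 8 lower, with Calb1 at 3.54, Pcp4 3.52, B3gat1 3.35, Sh3bgr 2.68, Rpl21 -0.33 and Btbd9 -2.13. Without stretch 1, 7 were higher and 2 lower, with Calb1 at 1.88, Pcp4 1.78, B3gat1 1.93 and Sh3bgr 1.19. Without stretch 2 Rpl29 had -0.13 and Mthfd2 -0.20, without stretch 3 Rpl29 had -1.69 and 3 genes were lower, and without stretch 5, 24 were higher and 8 lower.

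In neurons nearest type Ib, 5 genes were at least 2-fold higher and 0 lower in CKO. The call led by under 0.05 in 49 of 154 CKO neurons and 22 of 382 control neurons. These were Ceacam10 (log2 1.47), Sh3bgr (1.42), Ptgds (1.32), Lypd1 (1.26) and Mir6236 (1.19). The genes with the largest lower values were Rpl29 (-0.87), Lgals1 (-0.80), Rpl21 (-0.75), Rnf123 (-0.73) and the adhesion protein Parvb (-0.64). Without stretch 1 Lypd1 had 0.04 and Sh3bgr 0.81. Without stretch 2 Mir6236 had 1.99 and Rpl29 -0.17, without stretch 3 Rpl29 had -1.89 and Rpl21 -1.41, and without stretch 5 Ptgds had 2.34 and Mir6236 0.60. The counts were 10 higher and 3 lower without stretch 3, 9 and 1 without stretch 4, and 11 and 2 without stretch 5.

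In type II-like neurons, 7 genes were at least 2-fold higher and 1 lower in CKO. Coch, a matrix protein of the inner ear, had 413 UMIs in CKO, in 5.26% of cells, and 3 in control, a ratio of UMI rates of 106 (35.9 to 514). It had log2 2.78 and 0.04 without stretch 1. The growth factor Ptn (log2 1.59) had -0.13 and Cwc22 (1.29) 0.25 without stretch 1, while Ptn had 2.27 and Coch 3.57 without stretch 3. Eid2 (1.499) and Hddc3 (1.09) were also higher, the latter 0.46 without stretch 2 and 1.71 without stretch 5. Prph (-1.63), the 1 gene at least 2-fold lower, and with smaller values Cpne4 (-0.70) and the metalloproteinase Mmp14 (-0.68), were lower but had 0.62, 0.18 and 0.14 without stretch 2. The protease Tmprss3 had -0.79 and the lipid carrier Apoe, abundant in glia, -0.75. The counts were 2 higher and 3 lower without stretch 1, 3 and 0 without stretch 2, 11 and 7 without stretch 3, and 14 and 5 without stretch 5, with 2 lower without stretch 4.

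The leading clusters of a class differed in part between the 2 genotypes, with cluster 8 for type Ia and cluster 7 for type Ib among them in both. In CKO neurons nearest type Ib no cluster held more than 14.3%. Clusters 8, 0 and 1 held most of the CKO neurons nearest type Ia and clusters 15, 11 and 8 most of those in control, with clusters 12, 2 and 7 against 10, 17 and 7 leading for type Ib and 2, 12 and 1 against 13, 9 and 14 for type Ic. By their markers, clusters 12 and 2 are named type Ic (scores of 0.563 and 0.543, against 0.163 and 0.201 for type Ib) and cluster 1 type Ia, so the clusters that lead the CKO neurons nearest types Ib and Ic are in part named otherwise. Clusters 0, 1, 2, 5 and 18 held CKO cells only. Classes were called from the set genes, so values of set genes within a class are conditioned by the call.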

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

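Leaving out a column stretch and using glia-poor cells only were chosen after the results were seen, as were gene lists without type II-like cells and every test of Runx1 in neurons nearest type Ia. The other alternatives were planned. No paired analysis was possible because the cells carry no replicate number and no result comes from a test. Leaving out each library, DESeq2, camera, fry, a permutation over libraries and sets chosen in single control libraries were not run for the same reason. Depth limits shares of cells, since the CKO share with Calb1 was 47.5% at 10000 UMIs and 60.5% unthinned. Outside the stretches, 101 of the other values of main results stayed within their interval or within 1.5 times and 43 did not. For single genes and lists 243 stayed, 47 moved and 9 reversed. With a stretch left out, 52 stayed and 68 moved among main results, and 347 stayed, 54 moved and 14 reversed among genes and lists. The causes were not tested, except that a larger pseudocount lowers every fold and a filter sets how many genes enter.

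Of genes in all neurons, 6 were at least 2-fold lower with a pseudocount of 0.01, and 0 were higher with a pseudocount of 1 or the 5 times stricter filter. Without type II-like cells 5 were lower, as were 5 in glia-poor cells, where 4 lists lay outside the random range. With 1 stretch left out, 3 to 12 genes were higher, 1 to 11 lower, and 5 to 10 lists outside. The type Ib list had -0.21 with no filter. The type II list had -0.0047 and Plk5 -0.078 in glia-poor cells, and Prph, Th and Ngfr had 0.053, -0.012 and -0.031 without type II-like cells, where the type II, neurotrophin and ribosomal lists had -0.031, -0.031 and -0.036. With 1 stretch left out, the type II list ranged from -0.24 to 0.65, the glial list from -0.24 to 0.16 and the neurotrophin list from -0.017 to 0.15. Prph ranged from -1.61 to 0.80, Th from -0.25 to 0.72, Plk5 from -0.28 to 0.65 and Ngfr from -0.0155 to 0.39.

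The median log2 value of the type Ia set was 0.40 with 25 genes and 0.33 in glia-poor cells, where the type Ic set had -0.45. Leaving out 1 stretch gave 0.10 to 0.61 for type Ia, -0.36 to -0.19 for type Ib and -0.55 to -0.16 for type Ic. The CKO share nearest type Ib was 17.8% with a lead of at least 0.05 and 16.3% without 11 genes at least 2-fold apart within a class. In glia-poor cells the CKO share nearest type Ic was 12.7%, and the control shares nearest types Ia and Ib were 23.2% and 43.7%. With 1 stretch left out the CKO shares nearest types Ia, Ib and Ic ranged from 54.7% to 73.4%, 15.9% to 25% and 10.7% to 21.2%, and the control shares nearest types Ia and Ic from 12.04% to 37.2% and 24.6% to 45.0%.

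With at least 2 UMIs required, Calb1 was seen in 35.4% of CKO and 14.3% of control neurons, Lypd1 in 30.5% of control, and both in 5.77% and 0.467%. With no thinning the CKO and control shares were 60.5% and 39.7% for Calb1, 22.1% and 40.4% for Lypd1, and 15.2% and 11.1% for both. With 1 stretch left out, CKO shares ranged from 41.4% to 50.3% for Calb1, 13.2% to 24.4% for Lypd1 and 5.29% to 12.1% for both, and control shares from 25% to 44.0% for Lypd1 and 2.38% to 5.81% for both. The CKO share with Runx1 nearest type Ia was 56.4% with a lead of at least 0.05, 71.0% in glia-poor cells, and 53.3% to 68.9% with 1 stretch left out.

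Within classes, a pseudocount of 1 left 2 genes higher and 1 lower in type Ia, 0 higher in type Ib, 2 higher and 0 lower in type Ic and 0 higher in type II. The 5 times stricter filter left 1 higher and 1 lower, 1 higher, 2 higher and 0 lower, and 1 higher in the same classes. With no filter 18, 11 and 15 genes were higher in types Ia, Ib and II, and 2 lower in type Ic. With 1 stretch left out, 3 to 6 genes were lower in type Ia, 4 to 11 higher and 0 to 3 lower in type Ib, 7 to 24 higher and 1 to 8 lower in type Ic, and 2 to 14 higher and 0 to 7 lower in type II. Scg5 ranged from -1.15 to 0.86 in type Ia. In type II, Ptn ranged from -0.13 to 2.27, Prph from -2.21 to 0.62, Cpne4 from -1.06 to 0.18 and Mmp14 from -1.03 to 0.14.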

Other observations

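All tests in this part were chosen only after the results were seen. Among the CKO neurons nearest type Ia, the 290 with a Runx1 UMI after thinning differed from the 168 without in genes chosen after their values were seen. Calb1 had a mean of 2.89 with and 0.496 without Runx1, against 0.222 in control neurons nearest type Ia. The axonal ligand Ntng1 had 1.03 and 0.0838, against 0.0563 in control, and the glutamate transporter Slc17a6 1.11 and 0.322, against 0.233. The transcription factor Pou4f1 had 0.197 and 0.00720, against 0.00654. In control neurons nearest type Ib, the same genes had means of 1.39, 2.44, 2.19 and 0.175. Calb2 was high in both CKO groups, at 196 with and 250 without Runx1, against 237 in control neurons nearest type Ia and 62.8 in those nearest type Ib. The type Ia marker Rxrg had 0.291 with and 0.652 without Runx1, against 0.517 in control, so that cells with Runx1 lay below 0.306, the midpoint of control types Ia and Ib, and above 0.262, that of types Ia and Ic. B3gat1 had 2.30 and 1.95, against 2.09, and Pcdh20 0.311 and 0.369, against 0.463. Of the type Ic markers, Lypd1 had 0.206 and 0.0164, against 0.0163, and Grm8 0.0556 and 0.00212, against 0.00502. Control neurons nearest type Ic held far more of Lypd1, Grm8 and Pou4f1, at 35.5, 0.819 and 1.16. Ttn, a type Ib marker, stayed low at 0.128 and 0.0684, against 1.32 in control neurons nearest type Ib.

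Runx1 RNA was seen in 63.3% of CKO neurons nearest type Ia and in 13.2% of control ones. Free RNA is argued against, since 0 of 152 CKO type II-like cells held a Runx1 UMI at the same depth, where 3 counts would give 1.97% (exact upper bound 2.40%). Doublets with type Ib or Ic neurons would add UMIs, but the median UMI count with Runx1 was 0.997 times that without. Calls with a lead under 0.05 do not account for all of it, since 56.4% of the 381 other cells held Runx1. This is under the 63.3% of all, so cells with a smaller lead held Runx1 more often. A lead of 0.05 is also small beside the median of 0.242 in control neurons nearest type Ia, so uncertain calls stay open in part. More Runx1 RNA in neurons otherwise like type Ia was not settled over 91 type Ib and Ic set genes not given above. Their median log2 value with over without Runx1 was 0.223 in stretch 1 and 0.192 in stretch 3. The lower one lay between the bounds of 0.1 and 0.2 set for it. The medians were 0.435 and 0.418 over the type Ic genes and 0.0784 and 0.0194 over the type Ib genes. The same split of control neurons nearest type Ia gave 0.0764, 0.0739 and 0.0801 over all 91, the type Ic and the type Ib genes, so the type Ib values in CKO were no larger than in control. Of the 45 type Ic genes, 40 in stretch 1 and 43 in stretch 3 were higher with Runx1, against 27 in control. Taken alone, the type Ic genes thus go against neurons otherwise like type Ia, whereas the type Ib genes do not. The bounds were set for both sets together, and this reading by set was made after the values were seen. Cells with and without Runx1 were not matched on lead, so uncertain calls could raise type Ic genes as well, and the question stays open.

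In type I neurons, CKO cells of stretch 4 lay near control levels. On a scale from 0 (control) to 1 (the other CKO stretches), over 26 genes chosen without stretch 4, their median position was -0.205 (standard error over genes 0.0659), with 3 genes above 0.5, which were Ceacam10 at 0.936, Ptgds at 0.728 and Lgals1 at 0.505, and within types Ia (19 cells), Ib and Ic it was -0.0595, 0.133 and -0.101, with genes on the CKO side such as Rps2 at 0.905 (Ia) and 0.969 (Ic), Calb1 at 0.711 (Ib), Lgals1 at 1.58 (Ia) and Crym at 0.684 (Ic). For stretches 1 and 3 the scale places little, since its CKO end then holds stretch 4. Positions in type I neurons were 0.913 (3 genes, 0.573) and 0.0805 (8 genes, 0.336). By class, stretch 3 stood at 0.104 over 12 genes in type Ia, 0.653 over 9 in type Ib and 0.233 over 11 in type Ic. In type II-like cells it stood at 0.178 over 17 genes. At genes that set stretches 1 and 4 apart, stretch 3 thus lay near control in type Ia (standard error over genes 0.0999) and in type II-like cells (0.0371). In all type I neurons (0.336), type Ib (0.209) and type Ic (0.312) the standard errors were too large to place it. Lower depth is argued against by a median of 42800 UMIs in stretch 4, against 49000 and 42516 in CKO stretches 1 and 3. Control stretches 2 and 5 had 33694 and 44242. After thinning the position was -0.232, but thinning keeps mean levels in expectation and so could not decide. A wrong genotype label and Runx1 function kept under a right label cannot be told apart. Both put type I neurons near control, and only 3 genes set the other CKO stretches apart in type II-like cells. These lay on the CKO side at 0.63 to 0.71, but Igfbp6, 1 of the 3, was high in cells with glial RNA (7.84 against 0.025). Ceacam10 and Ptgds were high in such cells as well. The share of glia-high cells alone would not put these 2 genes on the CKO side, since it was 47.1% in stretch 4 and 49.0% and 71.3% in control stretches 2 and 5. Mean Ceacam10 in all neurons of these stretches was 0.740, 0.293 and 0.208, and mean Ptgds 1.07, 0.291 and 0.855. When the 5 stretches were parted 2 against 3, stretches 1 and 3 stood apart by at least 1.5-fold in 24 genes of type I neurons. The labelled genotypes stood apart in 2 (Calb1 and Ceacam10) and the next highest split in 14. Stretches 1 and 3 also led in type Ib with 10 genes and in type Ic with 39, against 6 for the next highest split in each. Stretches 1 and 4 led in type Ia with 9 genes, against 7 for stretches 1 and 3, and in type II-like cells with 12 against 0. Stretch 4 held only 19 and 23 cells there, so its means rest on few cells.

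Schwann and satellite glia RNA was present in 58.6% of neurons, and only 37 cells held between 2 and 10 glial UMIs per 10000. Abundant transcripts in glia-high cells included Pmp22 at 9.14 against 0.0292 in glia-poor cells and Mbp at 6.03 against 0.119. Free RNA would reach all droplets, but 40.2% of neurons held glial UMIs at under 0.1 times the mean rate of their stretch, against 3.29e-08% in Poisson draws at that rate. A Schwann cell or a fragment of one in the droplet, which a sort for tdTomato would keep when attached to a neuron, may account for it. Glia-high neurons held more UMIs in 14 of 15 groups of class and stretch, with a median ratio of 1.05, and no biological explanation was tested.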
